A study of Mus musculus with 10 samples.

How the data were processed

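Bulk RNA sequencing was available for inguinal white adipose tissue (iWAT), a subcutaneous fat depot, from 10 mice: 5 Sham mice injected with PBS and 5 PDAC mice that carried orthotopic pancreatic ductal adenocarcinoma cells. Groups and replicate numbers came from the sample titles. The authors deposited 1 table of raw read counts per gene, with 1 column per library, and all 10 columns were assigned to a sample. The deposited counts were whole numbers without normalization, as tested on the values. The submitters' processing notes named the mm10 build and DESeq2 without giving a role. The aligner, the counting program, the annotation release and the strand setting were not recorded, nor was the library kit. The protocol in the labels described RNA extraction and quantitative PCR but no sequencing library. Per the series' design text, the raw reads were lost, so alignment and counting could not be repeated.

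Gene coordinates and names were those of the deposited table. Of its 54532 genes, 99.93% were also in GENCODE M21, and 98.33% of those had an identical start and end there, so coordinates are given on mm10 (GRCm38). Because strand use in the counting was not recorded, genes that overlap or have near-identical copies, such as the haemoglobin, Serpina3 and Saa genes, have uncertain counts. Library totals ran from 24577689 to 30768585 counts, a ratio of 1.25. No pair of libraries was identical.

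Genes were filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3; minimum count 10, minimum total count 15), which left 17743 genes. Counts were scaled by TMM and tested with edgeR's quasi-likelihood test, PDAC against Sham, two-sided, without covariates. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the F statistic. CPM (counts scaled to a common library total) were computed from the TMM-scaled totals and are given as mean ± SD over 5 libraries per group. Principal components used the 500 most variable genes on log2 CPM with a prior count of 2, and group differences in component scores were tested by exact permutation, two-sided.

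Before the data were examined, 49 gene lists were fixed from general knowledge of adipose tissue, cachexia and other cell types. Of these, 48 had at least 5 genes past the filter and were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists. Each list's calls were also counted after adjustment over the list alone. Camera with an estimated correlation and fry were run beside it. After the data were seen, an exact permutation test of each list's score, its members' mean log2 CPM, was added and adjusted over 49 lists. This test permutes libraries, so it keeps the correlation between genes. Its smallest possible p is 0.00794.

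The rule for named genes was also fixed beforehand. It took Elavl1, the 12 largest rises and the 12 largest falls among called genes with a mean CPM of at least 5 and no overlap between groups, and up to 4 called members per list by smallest p. Where a list had no called member, the 2 members with the highest CPM were taken. Unnamed gene models, pseudogenes and immunoglobulin or T cell receptor segments were skipped.

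The gene and list tests were tested on simulated data first. Over 17743 simulated genes in 5 against 5 libraries, 49 of 100 genes changed 2-fold and 84 of 100 changed 4-fold were called, and 9 unchanged genes were called. All 5 simulated lists shifted 1.5-fold were called, and 0 of 15 other lists, in counts drawn without the correlation between genes that real libraries have.

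Alternatives covered scaling by DESeq2 size factors or upper quartiles, the DESeq2 1.42.0 Wald test, limma-voom with and without sample quality weights, other filters, other thresholds, a replicate block, scores of other tissues as covariates, and leaving out each library. Sets of libraries with or without skeletal muscle transcripts were added after the data were seen. Motifs in 3′ untranslated regions were counted on the GENCODE M21 models. Python 3.11.15 with scipy 1.17.1 was used for permutation tests of library measures.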

Results

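The data describe how a pancreatic tumour alters the transcriptome of inguinal white adipose tissue (iWAT), the main subcutaneous fat depot of the mouse. Wild-type C57BL/6J mice aged 12 to 15 weeks received either pancreatic ductal adenocarcinoma (PDAC) cells placed in the pancreas or PBS (Sham), with 5 mice in each group. The tumour cells carried mutant Kras and p53 under a Pdx1-driven Cre. Libraries held 24577689 to 30768585 counts, and totals did not differ detectably between the groups (n = 5 each; exact permutation test p = 0.19). Reads of the X-inactivation transcript Xist were few in all 10 libraries, at 2 to 25 counts, while the Y-linked Ddx3y had 2128 to 3730.

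Skeletal muscle transcripts varied widely between libraries within both groups. The skeletal muscle list took 1.17%, 1.89% and 0.84% of counts in Sham 1, 2 and 3, but 0.0354% and 0.00885% in Sham 4 and 5. In PDAC 1 to 5 the shares were 1.02%, 0.211%, 0.0285%, 0.0883% and 0.63%. The first principal component, with 55.5% of the variance, followed the muscle score across the 10 libraries (Pearson r = −0.961, Spearman rho = −0.988). Without the 2 libraries farthest from the median, r = −0.983. Permutation p = 1e-05 for both coefficients over all 10 libraries, the smallest value the random draws could give. Score and component come from the same expression values, so the correlation can be partly built in. The first component did not separate the groups (exact permutation p = 0.365). The second component, with 23.4%, did separate them (exact permutation p = 0.00794, adjusted p = 0.0318 over 4 components). None of the 19 skeletal muscle genes tested passed, with log2 fold changes of −0.53 ± 1.36 (SE) for Myh4 and −1.60 ± 1.21 for Acta1.

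**Figure D1:**
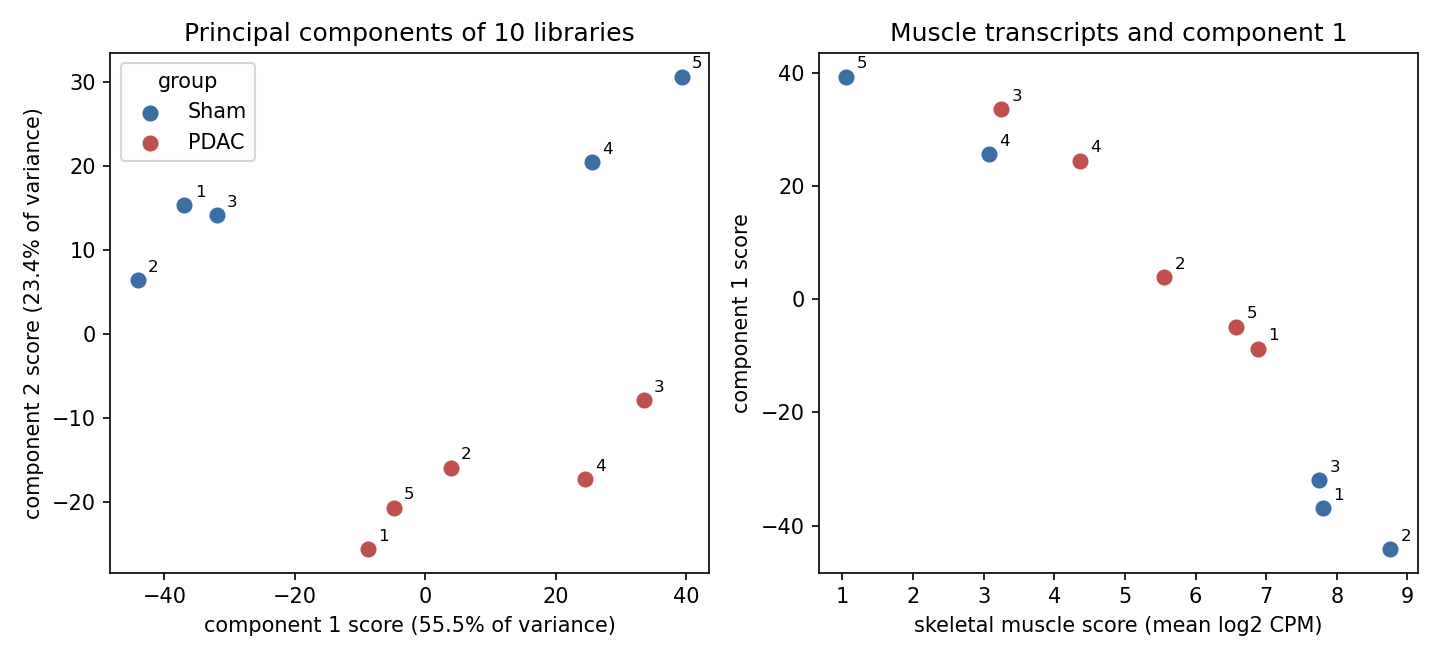
Left, scores of the 10 libraries on the first and second principal components; right, the skeletal muscle score (mean log2 CPM of the list) against the first component. Points are single libraries, blue for Sham and red for PDAC, numbered by replicate; the first component follows the muscle score (r = −0.961) and the second parts the groups.

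The comparison asked which iWAT genes differ when a pancreatic tumour is present. Of 23 de novo lipogenesis genes 9 were lower in PDAC and 0 higher, and of 26 macrophage genes 18 were higher and 1 lower, although neither list passed camera with an estimated correlation (adjusted p = 0.601 and adjusted p = 0.384). Scd1, the desaturase that makes monounsaturated fatty acids, fell 11.5-fold, from 19620 ± 7857 to 1705 ± 582 CPM (SD, n = 5 each). Cd163, a haemoglobin scavenger receptor of tissue macrophages, rose 4.62-fold, from 143 ± 31.7 to 659 ± 71.1 CPM. Of 17743 genes tested, 1861 were higher and 1636 lower in PDAC by edgeR's quasi-likelihood test at an adjusted p of 0.05. At least 2-fold changes were found in 591 higher and 519 lower genes. All PDAC libraries lay above all Sham libraries for 1436 genes and below them for 1148, or 14.6% of the genes against 0.794% by chance. The edgeR p-values set the group difference against the spread between libraries within the groups. The count depended on the libraries entered: without Sham 3 it was 1232 higher and 1048 lower. With only the 5 libraries low in muscle transcripts (Sham 4 and 5, PDAC 2, 3 and 4) it was 215 and 279, and with the other 5 it was 1828 and 1776.

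The study's title concerns HuR, the RNA-binding protein encoded by Elavl1 (ENSMUSG00000040028; chromosome 8, 4285382 to 4325413, minus strand, mm10). Elavl1 mRNA stood at 74.8 ± 6.25 CPM in Sham and 64.7 ± 7.02 CPM in PDAC (SD, n = 5 each), a log2 fold change of −0.21 ± 0.10 that did not pass edgeR's test (adjusted p = 0.152). With sample quality weights in limma-voom it passed (−0.24, adjusted p = 0.0436), and over all alternatives adjusted p ran from 0.0436 to 0.491. Protein, location and activity of HuR were not measured. Among 22 RNA-binding regulators of mRNA stability, 2 were higher, 3 lower and the others did not pass; adjusted over the list alone, 3 were higher and 4 lower. Fmr1, which encodes the fragile X protein, fell by 1.32 on the log2 scale (SE 0.19). Among 31 mRNAs commonly described as bound by HuR, 3 were higher and 4 lower (adjusted over the list alone, 3 and 5), and camera gave no direction (adjusted p = 0.368). Hmox1, the haem-degrading oxygenase, rose 4.86-fold within that list, while Insig1, a regulator of sterol synthesis, fell by 1.60 on the log2 scale (SE 0.32).

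List tests have a limit that applies to each list below. With camera's preset correlation, 11 lists were higher and 13 lower of 48 tested, but arbitrary splits of the same libraries often gave as many, and no list passed with an estimated correlation (lowest adjusted p = 0.384). Counts of called genes are therefore given for each list, to be set beside the 19.7% of all tested genes that were called. Some lists lie near that share, such as proliferation (5 of 27) and the respiratory chain (7 of 43). Genes of a list can move together (estimated correlation up to 0.916, for mitochondrially encoded genes), so called members are not separate pieces of evidence. In exact permutation tests of list scores, chosen after the data were seen, 9 of 49 lists passed, 5 higher and 4 lower, each at an adjusted p of 0.0432. Each had the smallest possible p of 0.00794, so the adjusted value depends on how many lists tie there. Some of these lists share genes, such as Adipoq, Cfd and Lpl in mature adipocyte markers and adipokines, so their passes are not separate. Score differences also depended on the libraries: in 15 of 49 lists they differed by over 2 SE between the 5 libraries low in muscle and the other 5, and in 12 of these the other 5 had the larger size. In 6 of the 15 the sign was opposite in the 2 sets. Neither set holds muscle constant: the skeletal muscle score difference was 2.32 (SE 1.14) among the 5 libraries low in muscle. Among the other 5 it was −1.38 (SE 0.436).

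Lipid synthesis genes were among the largest falls. Of 23 de novo lipogenesis genes, 9 were lower and 0 higher (adjusted over the list alone, 14 and 0). Fasn (chromosome 11, 120805846 to 120824547), the fatty acid synthase, fell by 4.06 on the log2 scale (SE 0.82), Scd1 (chromosome 19, 44394451 to 44407709) by 3.52 (SE 0.35) and the lipogenic regulator Thrsp by 3.45 (SE 0.50). Sham 2 held 13416 CPM of Fasn against 738 to 3152 in the other Sham libraries, and without Sham 2 the log2 fold change was −2.68 for Fasn, −2.75 for Thrsp and −1.57 for the malic enzyme Me1. The lipogenesis score difference was −0.331 ± 0.227 (SE) among the 5 libraries low in muscle and −1.41 ± 0.613 among the other 5. Triglyceride synthesis had 8 of 18 genes lower and 0 higher (adjusted over the list alone, 8 lower and 1 higher), including Dgat2, the final acyltransferase (−2.47 ± 0.37), and Mogat1 (−2.37 ± 0.27). Cholesterol biosynthesis had 16 of 23 lower and 0 higher (adjusted over the list alone, 18 and 0). Srebf2, the master regulator of sterol synthesis, fell 1.69-fold, from 149 ± 3.63 to 88.5 ± 4.83 CPM (adjusted p = 0.000168, edgeR). Camera called all of these lists lower at the preset correlation. With an estimated correlation adjusted p = 0.601 for de novo lipogenesis and adjusted p = 0.571 for the other lists. Only cholesterol biosynthesis passed the score test; de novo lipogenesis and triglyceride synthesis had an adjusted p of 0.0518 by exact permutation.

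**Figure D2:**
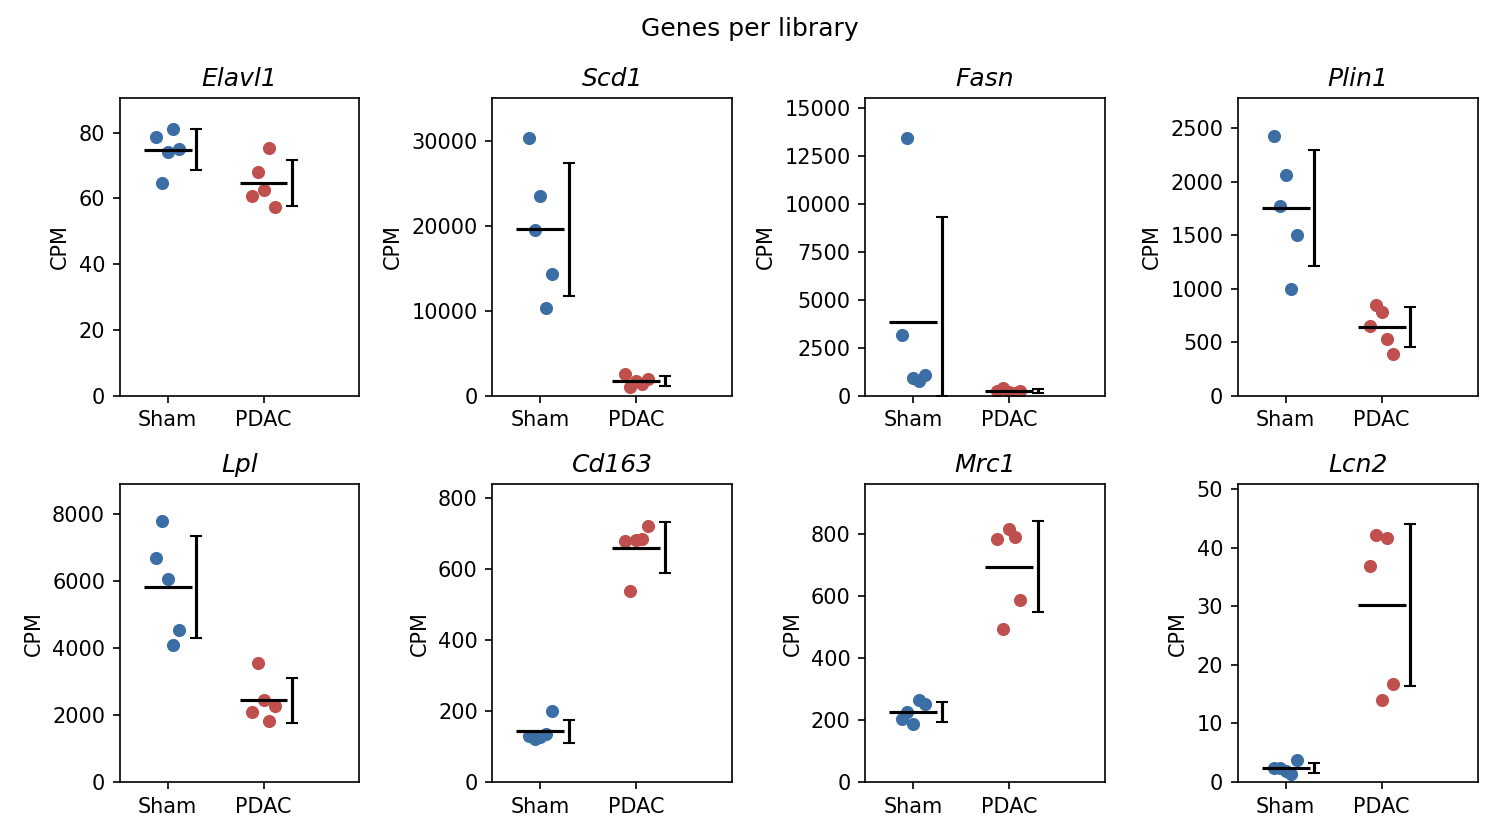
CPM of 8 genes in each library of Sham (blue) and PDAC (red); each panel has its own axis from 0, horizontal lines are means and bars are SD (n = 5), drawn no lower than 0. Elavl1 overlaps between groups, the 4 adipocyte genes Scd1, Fasn, Plin1 and Lpl lie lower in every PDAC library, and Cd163, Mrc1 and Lcn2 lie higher.

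Among 24 mature adipocyte markers, 12 were lower and 0 higher (adjusted over the list alone, 15 and 0). Plin1, the lipid droplet coat protein, fell 2.74-fold, from 1752 ± 545 to 640 ± 189 CPM. Lpl, the lipase that breaks down circulating triglyceride, fell 2.39-fold, from 5835 ± 1531 to 2439 ± 668 CPM. Aoc3 fell by 2.03 on the log2 scale (SE 0.27). The other 12 markers were not called over all genes. Among them were Adipoq (−0.73 ± 0.24, adjusted p = 0.052, edgeR), Fabp4 (−0.14 ± 0.16), Cfd (−0.16 ± 0.30) and Cidec (0.38 ± 0.26). The score difference was −0.543 ± 0.266 (SE) among the 5 libraries low in muscle and −1.26 ± 0.103 among the other 5. The list passed the score test and was called lower by camera (adjusted p = 0.571 with an estimated correlation). Adipokines and secreted factors had 8 of 22 lower and 0 higher (adjusted over the list alone, 14 lower and 1 higher; adjusted p = 0.384 with an estimated correlation), with Rbp4 at −1.99 ± 0.31. Insulin signalling had 9 of 24 lower and 2 higher (adjusted over the list alone, 13 and 3; adjusted p = 0.571 with an estimated correlation). In that list Grb14 fell by 2.41 on the log2 scale (SE 0.37) and Akt1 rose 1.52-fold. Both lists passed the score test. Adipocyte transcription factors had 5 of 18 lower and 1 higher (adjusted over the list alone, 5 and 2), and camera gave no call. Cebpa fell by 0.91 on the log2 scale (SE 0.18). Lipolysis had 7 of 22 lower and 3 higher (adjusted over the list alone, 8 and 4), again without a camera call. Ucp1, the uncoupling protein of brown fat, had 0 to 27 counts and was not tested.

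Several mitochondrial genes were lower in PDAC. Of 25 genes of the citric acid cycle and pyruvate metabolism, 14 were lower and 0 higher (adjusted over the list alone, 17 and 0), including Idh3a (−1.25 ± 0.22) and Mdh1 (−0.95 ± 0.20). Mitochondrially encoded genes had 9 of 12 lower and 0 higher (adjusted over the list alone, 12 and 0), with mt-Cytb at −1.25 ± 0.29. Mitochondrial transcripts took 4.4% ± 1.62 of counts in Sham and 2.26% ± 0.406 in PDAC (SD, n = 5 each; exact permutation p = 0.0159, adjusted p = 0.0476 over 6 library measures). Fatty acid oxidation had 10 of 25 lower and 1 higher (adjusted over the list alone, 12 and 2), with Acadm at −0.93 ± 0.16. Branched-chain amino acid catabolism had 8 of 23 lower and 0 higher (adjusted over the list alone, 13 and 0), with Mccc1 at −1.29 ± 0.18. The nuclear-encoded respiratory chain had 7 of 43 lower and 0 higher (adjusted over the list alone, 6 and 0). Camera called these 5 lists lower, and with an estimated correlation the adjusted p was 0.601 for fatty acid oxidation, 0.678 for the respiratory chain and 0.571 for the others. None of the 5 passed the score test. These differences were smaller among the 5 libraries low in muscle (2 Sham, 3 PDAC): the score difference was −0.12 ± 0.177 (SE) for the citric acid cycle against −0.845 ± 0.209 among the other 5, and −0.234 ± 0.248 against −1.5 ± 0.189 for mitochondrially encoded genes. The respiratory chain list turned to higher, without a call, among the 5 libraries low in muscle (adjusted p = 0.581, camera). The skeletal muscle score also differed between the groups within these sets, higher in PDAC in the low set and lower in the other.

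Most macrophage genes rose. Of 26 genes, 18 were higher and 1 lower (adjusted over the list alone, 19 and 2), with a median log2 fold change of 1.40. Cd163 (chromosome 6, 124304656 to 124330527) rose by 2.21 ± 0.16 on the log2 scale, Clec10a by 2.17 ± 0.24, Lyve1 by 1.87 ± 0.17 and the mannose receptor Mrc1 by 1.61 ± 0.17. The list passed the score test and was called higher by camera (adjusted p = 0.384 with an estimated correlation). Fcna (8.8-fold), Vsig4 (7.36-fold) and Fcgr4 (7.76-fold), which encode a ficolin, a complement receptor and an Fc receptor, were among the 12 largest rises. So were Chil3 (10-fold) and Arg1, the arginase of alternatively activated macrophages (15.2-fold; log2 3.93, or 3.09 without PDAC 2). Neutrophil genes had 7 of 16 higher and 1 lower (adjusted over the list alone, 10 and 1; adjusted p = 0.571 with an estimated correlation), with Retnlg at 1.91 ± 0.32. Erythroid genes, which mark blood, were higher too: 4 of 5 passed (score difference 0.93, SE 0.234; exact permutation p = 0.0159, adjusted p = 0.0518). Dendritic and mast cell genes had 5 of 21 higher and 1 lower (adjusted over the list alone, 6 and 1; adjusted p = 0.384 with an estimated correlation), led by Fcer1a (2.27 ± 0.26), and passed the score test.

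None of the 20 B cell and plasma cell genes passed by edgeR, over all genes or adjusted over the list alone, and Igkc stood at −0.31 ± 0.16. T and NK cell genes had 2 of 24 higher and 3 lower (adjusted over the list alone, 4 and 6), with Gzma at 1.20 ± 0.22 and Cd4 at −0.69 ± 0.16. Interferon-stimulated genes had 5 of 38 lower and 0 higher (adjusted over the list alone, 4 and 0), with Ifi27 at −0.76 ± 0.16. Camera called none of these 3 lists. The T and NK cell score difference was −0.554 ± 0.115 (SE) among the 5 libraries low in muscle and 0.301 ± 0.0843 among the other 5, and that of B cells −0.546 ± 0.33 and 0.257 ± 0.131.

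Acute phase genes had 10 of 20 higher and 3 lower (adjusted over the list alone, 12 and 3). Lcn2, an iron-scavenging lipocalin, rose 12.8-fold, from 2.36 ± 0.86 to 30.2 ± 13.8 CPM, and Serpina3m rose 14.2-fold. Orm1, an acute phase glycoprotein, went the other way and fell 15.1-fold, from 73.5 ± 28.1 to 4.88 ± 3.22 CPM. Saa3 rose 7.43-fold (adjusted p = 0.0245, edgeR) but did not pass without Sham 1, PDAC 1 or PDAC 4 (adjusted p = 0.053, 0.06 and 0.057, edgeR). The list passed the score test and was called higher by camera (adjusted p = 0.384 with an estimated correlation). IL-6 and STAT3 response genes had 8 of 21 higher and 0 lower (adjusted over the list alone, 8 and 0; adjusted p = 0.571 with an estimated correlation), including Osmr, the oncostatin M receptor (0.81 ± 0.09). The IL-6 and STAT3 list did not pass the score test (adjusted p = 0.0972, exact permutation). Its score difference was 0.273 ± 0.153 (SE) among the 5 libraries low in muscle and 0.767 ± 0.202 among the other 5. Among 34 cytokines and chemokines, 10 were higher and 5 lower (adjusted over the list alone, 11 and 7), with no camera call. That list did not pass the score test either (adjusted p = 0.43, exact permutation). Its score difference was −0.253 ± 0.343 among the 5 libraries low in muscle and 0.671 ± 0.35 among the other 5. Ccl8 rose 7.27-fold and Ccl6 6.09-fold.

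**Figure D3:**
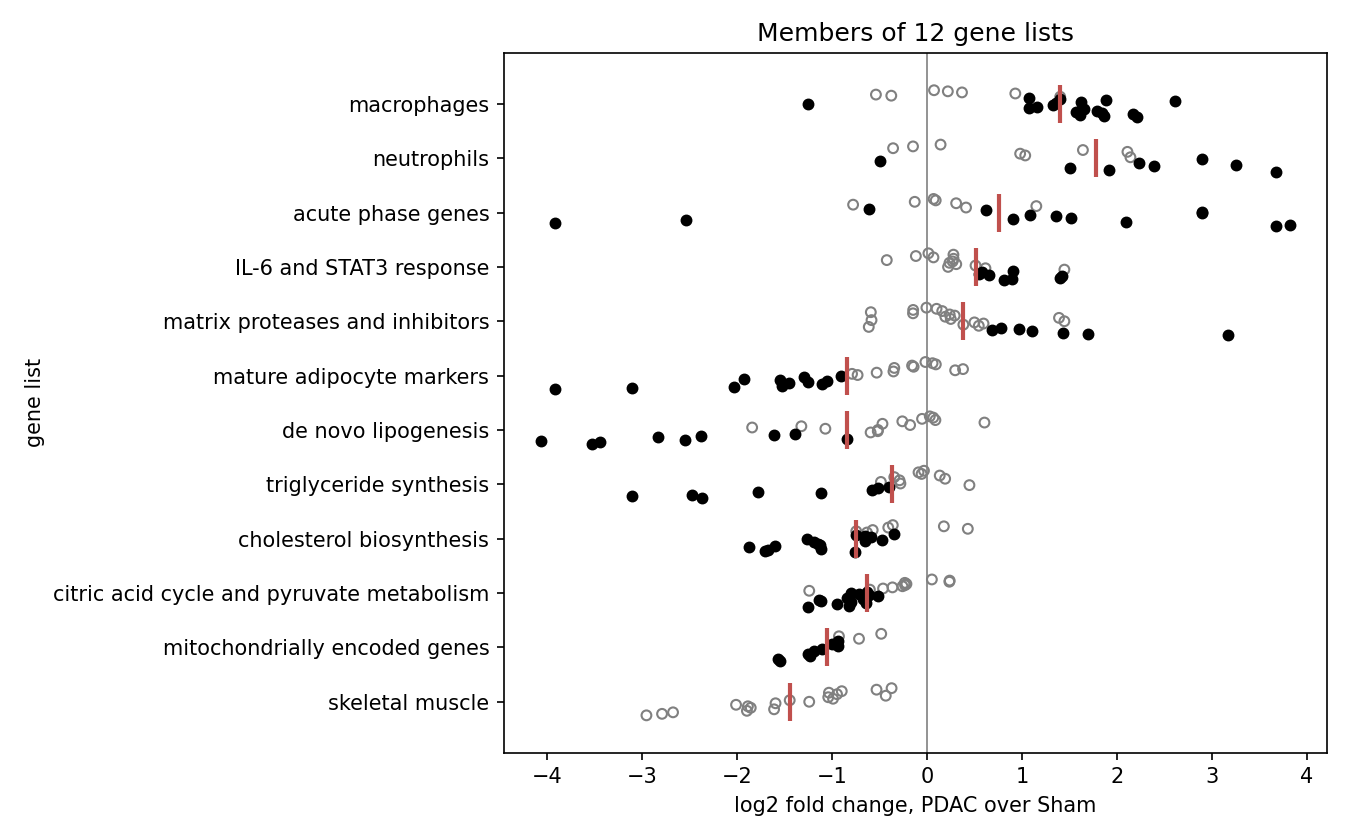
Log2 fold changes (PDAC over Sham, x axis) of the tested members of 12 gene lists (y axis); filled points passed edgeR's test at an adjusted p of 0.05, open points did not, and red bars are list medians. Macrophage genes have a median of 1.40 and citric acid cycle genes one of −0.63; no skeletal muscle gene passed.

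Stromal genes moved in both directions. Matrix proteases and inhibitors had 7 of 25 higher and 0 lower (adjusted over the list alone, 9 and 1; adjusted p = 0.571 with an estimated correlation), led by Mmp11, a stromal metalloproteinase that rose 9.03-fold from 12.2 ± 3.59 to 110 ± 33.1 CPM. The score difference of that list was 0.166 ± 0.312 (SE) among the 5 libraries low in muscle and 0.92 ± 0.17 among the other 5. Collagens and matrix had 4 of 34 higher and 4 lower (adjusted over the list alone, 4 and 4), with Lox at 1.22 ± 0.18 and Col15a1 at −1.55 ± 0.28. Progenitor and fibroblast genes had 3 of 25 higher and 6 lower (adjusted over the list alone, 3 and 7). Endothelial genes had 7 of 22 higher and 0 lower (adjusted over the list alone, 7 and 0; adjusted p = 0.571 with an estimated correlation), with Sox17 at 0.86 ± 0.14, and passed the score test; Lyve1 belongs to this list and to the macrophage list. Smooth muscle and pericyte genes had 4 of 16 lower and 0 higher (adjusted over the list alone, 7 and 0; adjusted p = 0.571 with an estimated correlation), with Rgs5 at −1.25 ± 0.19. The largest rise overall under the naming rule was Prg4, the lubricin gene (16.5-fold; log2 4.05, or 4.78 without Sham 5). The hypoxia response list had 2 of 18 higher and 2 lower (adjusted over the list alone, 2 and 2). It had no camera call (adjusted p = 0.986) yet passed the score test, with a median of −0.02 and a mean of 0.21 that differ in sign, and its Adm, which encodes adrenomedullin, rose 7.76-fold.

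Immediate early genes had 8 of 24 lower and 0 higher (adjusted over the list alone, 8 and 0; adjusted p = 0.678 with an estimated correlation). Nr4a1 fell 4.12-fold, from 65.4 ± 19.6 to 15.9 ± 1.7 CPM, and Fosb fell 9.28-fold. Erythroid genes had 4 of 5 higher (adjusted over the list alone, 5; adjusted p = 0.571 with an estimated correlation), with Hba-a2 at 1.25 ± 0.25. Proliferation genes had 5 of 27 higher and 0 lower (adjusted over the list alone, 7 and 0; adjusted p = 0.63 with an estimated correlation), with Aurkb at 1.09 ± 0.24. Antigen presentation had 5 of 17 higher and 0 lower (adjusted over the list alone, 5 and 0; adjusted p = 0.601 with an estimated correlation), with Psmb8 at 0.60 ± 0.12. The unfolded protein and integrated stress response had 2 of 22 higher and 1 lower (adjusted over the list alone, 6 and 1; adjusted p = 0.571 with an estimated correlation), with Edem1 at −0.63 ± 0.12. Of 9 pancreatic tumour and acinar genes, 2 were higher (adjusted over the list alone, 5), without a camera call. Camera gave no call for the remaining lists. Thermogenic and beige genes had 7 of 20 lower and 1 higher (adjusted over the list alone, 8 and 1), and glycolysis had 4 of 19 lower and 0 higher (adjusted over the list alone, 4 and 0). Fatty acid uptake had 5 of 18 lower and 3 higher (adjusted over the list alone, 6 and 4), with the caveolar protein gene Cav1 at −1.94 ± 0.22 and Lrp1 at 1.02 ± 0.14. The glycolysis and fatty acid uptake lists differed in sign between library sets: the score difference was 0.146 ± 0.0697 (SE) for glycolysis and 0.0928 ± 0.0813 for fatty acid uptake among the 5 libraries low in muscle, and −0.502 ± 0.17 and −0.363 ± 0.0528 among the other 5. The glucocorticoid and fasting response had 5 of 24 higher and 4 lower (adjusted over the list alone, 5 and 4), with the metallothionein Mt1 at 2.21 ± 0.33. Autophagy and ubiquitin proteolysis had 4 of 25 higher and 2 lower (adjusted over the list alone, 6 and 3), with the protease Ctsl at 1.07 ± 0.19. Other large falls were those of Tmem45b (16.7-fold), Cdsn (11.1-fold), Npr3 (7.23-fold), Gpt (7.12-fold) and Pon1 (7.73-fold).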

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

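The tests of cell makeup and blood, the comparisons within libraries low in muscle and the tests of lipogenic genes against adipocyte genes were chosen after the results were seen. The tests with the muscle score and the splits of the libraries were set before.

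In 158 sets of 5 libraries, 11 had a library whose gap to the next, divided by the range of its group, exceeded the limit for 5 samples. Chance alone marks about 1 in 20 such sets. PDAC 2 was highest of its group in 6 of them: the scores of lipolysis (gap over range 0.862), fatty acid oxidation (0.81), branched-chain amino acid catabolism (0.763), mammary epithelium (0.72) and pancreatic tumour and acinar genes (0.721), and Arg1 (0.751). PDAC 3 was lowest in the erythroid score (0.893). Sham 5 was highest in Prg4 (0.854) and PDAC 4 in Vsig4 (0.732). Sham 2 was highest in Fasn (0.81) and Thrsp (0.775).

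With the skeletal muscle score in the fit, the lower lipogenesis score kept a difference of −0.916 (SE 0.299) against −0.972 without it. Leaving out Sham 2, it was −0.676 (SE 0.18) against −0.645. This met the bound set beforehand against muscle as the cause. The muscle score itself differed little between the groups (−0.366, SE 1.669). The fit could therefore hardly move the difference, and muscle stays open. The difference was smaller among the libraries low in muscle (−0.331, SE 0.227) than among the others (−1.41, SE 0.613, or −0.966 without Sham 2), a gap of 1.08 (SE 0.654) that stays within 2 SE. Fewer adipocytes could lower these genes too. The whole list fell little more than 8 adipocyte genes outside lipid synthesis (excess −0.336, SE 0.312; exact permutation p = 0.365), of which only Aoc3 and Plin1 were called, so the explanations cannot be told apart on the list. A further test, run after that result, took only the 9 called genes and gave −1.43 (SE 0.424), but those genes were picked for being lower, which favours such an excess, and it settles nothing.

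Muscle and fewer adipocytes were each tested as causes of the higher macrophage genes, with limits. With the muscle score as a covariate the score difference was 1.16. This met the bound set beforehand, but the muscle score differed little between the groups (−0.366, SE 1.669). The fit could therefore hardly move the difference. Macrophage scores were higher in PDAC both among the libraries low in muscle (0.955, SE 0.31) and among the others (1.34, SE 0.107). The muscle score differed in opposite directions in these sets (2.32, SE 1.14, and −1.38, SE 0.436), which argues against muscle as the cause. Fewer adipocytes would raise every other cell type alike, but the macrophage score exceeded the mean of the endothelial, smooth muscle and fibroblast scores by 1.32 (SE 0.167). Those reference scores did not move alike, with differences of 0.3, −0.385 and −0.315, so their mean is a loose yardstick. The macrophage difference of 1.19 (SE 0.168) was also larger than the endothelial one, although these lists share Lyve1. Blood would leave genes of tissue macrophages near 0, but 9 such genes had a median log2 fold change of 1.79. The group difference in their mean score had an SE of 0.184. These 9 genes were picked after the results were seen and include Fcna and Vsig4, which are among the 12 largest rises. Such a choice favours a high median, so the test speaks against blood for these genes only. More macrophages in the tissue, or more transcripts per macrophage, may account for the rise, a hypothesis found and tested on the same libraries. Blood was not excluded for the neutrophil genes or for the other macrophage genes.

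The lower citric acid cycle genes kept 93.8% of their score difference with the muscle score in the fit (−0.509, SE 0.138), which met the bound set beforehand against muscle as the cause. Among the libraries low in muscle, however, the difference was −0.12 (SE 0.177), against −0.845 (SE 0.209) among the others, a gap of 0.726 (SE 0.274). The fit assumes 1 group difference at every muscle level, which that gap speaks against, so muscle stays open. The sets do not isolate muscle either: its score difference was 2.32 (SE 1.14) among the libraries low in muscle and −1.38 (SE 0.436) among the others. A lower share of adipocytes may also contribute, but the 8 adipocyte genes ran from −2.03 for Aoc3 to 0.38 for Cidec with 2 called lower and 6 not called, so they did not fall together and do not decide it.

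Chance alone was unlikely to give the gene counts, although 100 splits cannot show a share below 1 of 100. Of 100 splits of the 10 libraries, 1, the real one, gave as many higher genes (1861) and 1 as many lower genes (1636), and the highest of the others gave 121. That other split followed the muscle transcripts. Chance could not be excluded for the list counts by camera's preset correlation: 62 of 100 splits gave as many lists in one direction as the 11 higher lists, and 46 of 100 as many as the 13 lower ones, with up to 21 in another split. The number of lists called by that test is therefore no evidence of a group effect.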

How the results depend on the processing

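The library sets by muscle content, and the estimated correlation with the muscle score, were chosen after seeing the data. The 3497 called genes kept their direction under every scaling, test, covariate and left-out library in which they were tested. Among the libraries low in muscle 99.83% kept their direction, but only 10.35% kept their call. The genes were called on these same libraries, so a kept direction is largely fixed in advance. With the muscle score as a covariate 99.2% kept their call. Counts of higher and lower genes were 3146 and 2876 with sample quality weights, 808 and 588 at an adjusted p of 0.01, and 293 and 211 against a fold of 1.5 (glmTreat). Leaving out 1 library gave 1232 to 2046 higher and 1048 to 1888 lower, the lowest without Sham 3. With only the 5 libraries low in muscle they were 215 and 279, but 1828 and 1776 with the other 5, so the number of libraries alone does not account for the drop. Without Sham 4 and Sham 5 they were 2730 and 2609. The cause was not tested. Lists higher and lower numbered 0 and 0 by camera with an estimated correlation, also with the muscle score, and 7 and 3 by fry. Leaving out 1 library gave 10 to 12 higher and 13 to 17 lower lists. Among the libraries low in muscle, the respiratory chain list turned to higher without a call (adjusted p = 0.581, limma camera) and skeletal muscle was called higher (adjusted p = 1.2e-05, limma camera). In that setting 10 other lists lost their call and 7 gained one, and 114 named genes lost theirs. Elavl1 passed only with quality weights (−0.24) and ranged from −0.31 to −0.17 otherwise; without 1 library it was −0.28 to −0.17. The first component did not separate the groups under any setting (p = 0.0556 to 0.754 by exact permutation without 1 library). Of 177 genes under the naming rule, 170 were called and 52 of them kept the call in every setting. Signs changed without any call in 12 of 167 gene values and 55 of 576 list values. Depth limits genes with few counts, such as Ucp1.

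A replicate block gave 1577 higher and 1381 lower genes, 12 and 16 lists, and −0.21 for Elavl1. With the block 78.41% of the main calls were kept. The numbers gave no clear pairing of the libraries. Deviations of same-numbered libraries correlated at 0.122, 0.206, −0.211, 0.12 and −0.182, and no Sham library correlated best with the PDAC library of its own number.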

Other observations

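The tests of gene families, of base composition and of the motif correlation in other splits were chosen after seeing the data, and the motif correlation itself was set before. Genes were grouped by symbol into 269 families. Among ribosomal protein genes, of 50 Rpl genes 19 were higher and 0 lower, with a median log2 fold change of 0.37, and of 46 Rps genes 11 were higher and 2 lower (median 0.31). Host genes of small nucleolar RNAs (Snhg) had 7 of 13 higher and C-type lectins (Clec) 6 of 24, with 0 lower in both. By camera these 4 families passed at the preset correlation (adjusted p = 5.71e-08, 0.00639, 0.00924 and 0.00924), and none passed with an estimated correlation (adjusted p = 0.999). Ribosomal protein genes have many near-identical copies that counting can mix.

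HuR binds AU-rich elements in 3′ untranslated regions, so ATTTA motifs were set against the fold changes. Across 14500 genes with an annotated region, 81.9% of those tested, Spearman's rho was −0.189, and genes are not independent replicates. This met the size of 0.1 set beforehand. Given region length and expression, rho was −0.136, and the T-rich motif TTTNTTT gave −0.148. Checks added afterwards weakened the ATTTA correlation. AT content alone gave −0.215, and rho for ATTTA was −0.0393 given region length, expression and AT content. Of 100 splits of the libraries, 8 gave a rho as large, with up to 0.227 in another split. A motif effect may be present, but base composition and differences between libraries cannot be told apart from it.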
